A study of Homo sapiens with 6 samples.

How the data were processed

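RNA of MDA-MB-231 cells treated with control siRNA (3 arrays) or LSD1 siRNA (3 arrays) was measured on Affymetrix expression arrays, from 2.5 ug of total RNA per array. The authors deposited linear signal intensity values for 54675 probe sets on each array. Per the submitters' processing notes, GCOS, Affymetrix Expression Console 1.1 and MAS5 were used. The trimmed mean of the deposited intensity values is 500.1 on each array, so a common scaling is already in them. The values used here carry no detection calls. Scaling to a common mean removes any difference in total RNA per cell, and MAS5 signals are noisy at low intensity.

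Gene names came from the platform annotation, matched by gene identifier to a RefSeq table used for names only, so no coordinates are given. Of the probe sets, 41097 have 1 gene symbol, 1801 have several and 11777 are not listed; of the first kind, 41043 matched the table and 0 symbols needed updating. The 62 control probe sets and all probe sets without exactly 1 symbol were left out of the gene test. Each gene was represented by its probe set with the highest mean, and sets with the x suffix, 1 of the marks of possible cross-hybridisation, were used only where a gene had no other. Sets with other suffixes were treated alike, and MEX3D is represented by a set with the f suffix. Values were taken as log2(signal + 15), where 15 is the 25th percentile of all signals. Genes with a mean above the 40th percentile of all probe sets were kept, a signal of about 28.0, which left 13825 genes. A log2 change is on this shifted scale and understates the change of dim genes.

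Groups were compared with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with an intensity trend, no covariate, and Benjamini-Hochberg adjustment at 0.05 over all genes tested. All limma tests are two-sided. The 28 gene lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. They were tested again with an estimated correlation and with fry, which asks whether a list's genes move one way on balance and does not compare them with other genes. With an estimated correlation, camera also uses the residual degrees of freedom of the arrays in place of those of all genes tested. A list can therefore lose its call there without its members moving together. Of 777 list members, 55 had no probe set named here and 62 were below the filter. The lists, tests and alternatives were chosen before the data were examined.

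The named genes are KDM1A, the 12 largest rises and 12 largest falls past the threshold whose groups do not overlap, up to 4 members with the smallest p past the threshold from each list, and CDKN1A, CCNA2, ERBB2, MKI67, CDH1, VIM and EGFR whatever their result. Other list members named were chosen after their values were seen: the few that went against their list, and ANP32E, BAX, MDM2, NFKB1, RELB, TNF, HERC5, IFITM1, ISG15, OAS3, CXCR4, TIMP1, TIMP2, RBL1, ESR1, ENO1, LDHA, PKM, CD14 and CD3E. Alternatives covered the constant added to the signal (1 and 60), the filter, quantile normalization, median centring, the variance model, a replicate block, the mean of all probe sets, every probe set tested, an unmoderated test and leaving out each array.

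The gene test was tested on simulated data for this comparison over 13825 genes, with 50 genes changed at each size. It recovered 8% of changes of 1.25-fold, 46% at 1.5-fold, 64% at 2-fold and 74% at 3-fold, with 4 false calls. Of the brighter genes, 4 of 21 were recovered at 1.25-fold, 20 of 25 at 1.5-fold, 23 of 23 at 2-fold and 20 of 22 at 3-fold. In the real comparison 41.0% of genes passed, a far larger share than was changed in the simulation. With few changed genes the adjustment asks for a smaller p, so these shares do not give the recovery in the real data. The set test called the 1 list shifted in a simulation and 0 others. Genes varied independently there, so it does not show how the test behaves where members move together. The ribosomal protein list, for example, had an estimated correlation of 0.83. Figures were drawn with matplotlib 3.10.9.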

Results

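Gene expression was measured on 6 microarrays in MDA-MB-231, a human breast cancer cell line without estrogen receptor expression. The cells received either a control siRNA or an siRNA against LSD1, with 3 biological replicates each. LSD1, encoded by KDM1A, is a histone demethylase that removes methyl groups from lysine 4 of histone H3. Total RNA was taken after 6 days and 2 rounds of transfection, and the comparison asks which transcripts differ when LSD1 is depleted. Each array gives a signal for 54675 probe sets, and its trimmed mean signal is 500.1 on all 6 arrays. Arrays hold no read depth, so the number of arrays limits the precision. The median standard error of a log2 change was 0.11.

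KDM1A, the targeted gene, fell to 9.58% of its control signal. Its signal was 2443 ± 130 (SD, n = 3) with control siRNA and 234 ± 53.6 (SD, n = 3) with LSD1 siRNA. The log2 change was -3.32 with a standard error of 0.13 (limma adjusted p = 1.46e-08). The 3 LSD1 siRNA arrays lay between 184 and 291 and the 3 control arrays between 2295 and 2540. An exact two-sided permutation test of the 6 values gave p = 0.1, the smallest that 3 against 3 arrays allow. KDM1A has 1 probe set here.

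**Figure D1:**
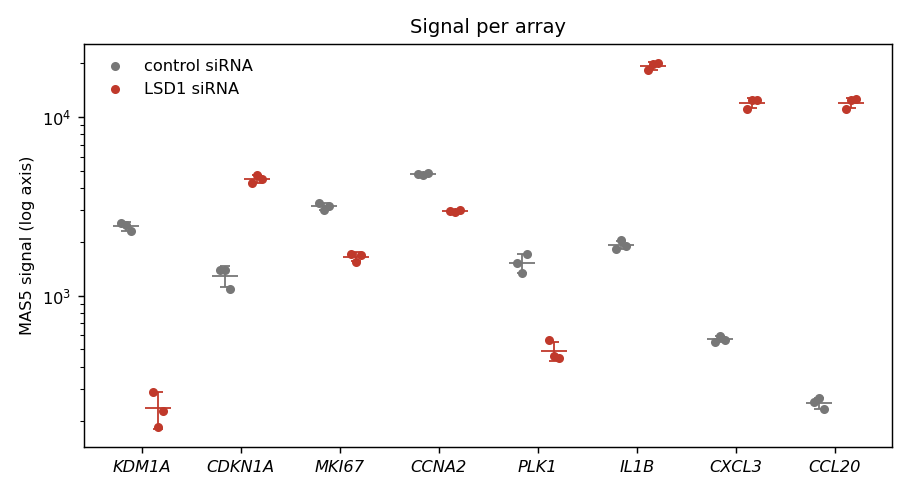
Signal of 8 genes on each of the 6 arrays, on a log axis, with control siRNA in grey and LSD1 siRNA in red; points are arrays, horizontal marks are means and bars are SD (n = 3). KDM1A, MKI67, CCNA2 and PLK1 lie lower on all 3 LSD1 siRNA arrays, and CDKN1A, IL1B, CXCL3 and CCL20 lie higher, CCL20 at 12006 against 250.4 in the control arrays.

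Chemokine and interleukin genes were among the highest rises, and genes of DNA replication and mitosis were among the falls. PI3, which encodes the elastase inhibitor elafin, rose by 5.67 on the log2 scale, from a signal of 59.4 ± 6.99 to 3755 ± 75.4 (SD, n = 3). CCL20, a chemokine gene, rose by 5.50, and CXCL3, another chemokine gene, rose by 4.35. SPP1, which encodes osteopontin, rose by 4.28, and IL1A, which encodes interleukin-1 alpha, rose by 3.91. Among the falls after KDM1A were CDT1 (-1.76) and CHAF1A (-1.73), which act in DNA replication and chromatin assembly, and PLK1 (-1.61), a mitotic kinase.

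Of 13825 genes tested with limma, 5674 changed at an adjusted p of 0.05, which is 41.0% of them. Of these, 2735 were higher and 2939 were lower with LSD1 siRNA. Changes of at least 2-fold were found for 448 higher and 193 lower genes, and changes of at least 4-fold for 62 higher and 3 lower genes. The arrays of the groups did not overlap for 50.4% of the genes tested, where chance gives 10%. With the mean of all probe sets of a gene in place of its brightest one, 4420 genes passed, 3921 of them among the 5674.

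The other rises among the 12 largest were ABAT (3.77), EHF (3.72), CSF3 (3.62), F2RL2 (3.43), C1S (3.38), MLLT11 (3.38) and BCL2A1 (3.38). EHF is an epithelial transcription factor, CSF3 encodes a granulocyte growth factor and BCL2A1 an inhibitor of apoptosis. ABAT and C1S had control signals of 5.46 ± 5.78 and 16.3 ± 21.2 (SD, n = 3), so their folds rest on dim control values. With a constant of 1 in place of 15, another ABAT probe set became the brightest and gave a log2 change of 0.70 (adjusted p = 0.231), while the probe set used here gave 5.69. The other falls were TEDC2 (-2.51), HES6 (-2.06), VASH2 (-1.80), ITFG2 (-1.76), MEX3D (-1.65), KLHDC3 (-1.64), ITPKA (-1.63), RAD54L (-1.62) and FAM81A (-1.59). TEDC2 ended at a signal of 53.3 ± 46.7 (SD, n = 3), and TEDC2, ITFG2 and FAM81A had adjusted p of 0.0675, 0.0579 and 0.0820 in the unmoderated test. VASH2, ITPKA, HES6 and FAM81A ended lower still, at mean signals of 16.6, 18.7, 34.3 and 34.8, so their folds rest on dim values too. With the mean of all probe sets, MEX3D was at -0.27 (adjusted p = 0.328), while SPP1 (2.53), IL1A (1.87), ABAT (2.32), EHF (1.62), VASH2 (-0.9997), ITFG2 (-0.65) and CHAF1A (-0.89) passed with smaller changes.

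**Figure D2:**
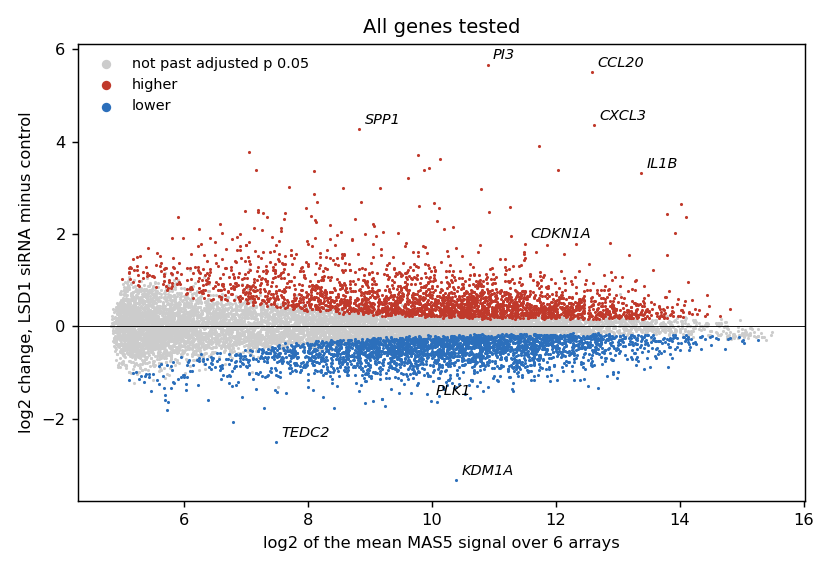
Log2 change of each of the 13825 genes tested, LSD1 siRNA minus control siRNA, against the log2 of its mean signal over the 6 arrays; red and blue points passed an adjusted p of 0.05 and grey points did not. The highest rises reach 5.67 (PI3) and 5.50 (CCL20), while the lowest point, KDM1A, is at -3.32.

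Genes of DNA replication and mitosis fell together. All 41 measured S phase genes fell, both over all genes and when adjusted over the list alone, with a median log2 change of -0.86. UHRF1, which maintains DNA methylation at replication, fell from 7422 ± 178 to 3299 ± 187 (SD, n = 3), a change of -1.17. UNG, a uracil-removing repair enzyme, changed by -1.17, CDCA7 by -1.15 and GINS2, part of the replicative helicase, by -1.16. Of 57 G2 and M phase genes, 54 fell, and 55 fell when adjusted over the list alone. The kinetochore genes CENPF (-1.18) and CENPE (-1.07), the spindle gene TPX2 (-1.02) and the ubiquitin-conjugating enzyme gene UBE2C (-0.98) were among them. ANP32E, a histone chaperone gene, rose by 0.25, with an adjusted p of 0.0671 without control replicate 2, 0.0817 without LSD1 siRNA replicate 2, 0.0694 with no intensity trend and 0.0842 in the unmoderated test. CCNA2, the cyclin A2 gene, changed by -0.69 and the proliferation marker MKI67 by -0.93. Both lists passed the camera set test with its preset correlation. They also passed with an estimated correlation, with adjusted p = 0.0294 for S phase and adjusted p = 0.0282 for G2 and M phase.

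Of 16 measured genes in a list of cyclins, CDKs and CDK inhibitors that also holds MYC, RB1, RBL1 and RBL2, 2 rose and 9 fell over all genes, and 3 rose and 9 fell when adjusted over the list alone. CDKN1A, which encodes the CDK inhibitor p21, rose from 1294 ± 172 to 4493 ± 229 (SD, n = 3), a log2 change of 1.79. CCND2 rose by 0.71, while CCND1 changed by -0.71 and CCNE1 by -0.90. CCNE1 was at -0.26 with the mean of its probe sets (adjusted p = 0.237). RBL1, a relative of the retinoblastoma gene, is among the 9 at -0.74. The list did not pass camera (adjusted p = 0.0764). Of 20 p53 target genes, 9 rose and 1, BAX, fell, and 10 rose and 1 fell when adjusted over the list alone. TP53I3 rose by 1.01, GADD45A by 0.65 and TNFRSF10B, a death receptor gene, by 0.35, while MDM2 had a value of 0.30 that did not pass. The p53 list passed camera, and had an adjusted p = 0.107 with an estimated correlation. Of 25 apoptosis regulators, 13 rose and 5 fell, the same counts as when adjusted over the list alone. They act in opposite ways: BCL2A1 (3.38) inhibits apoptosis, BIK (1.58) and the receptor TNFRSF10A (0.90) promote it, and the inhibitor BIRC5, also a mitotic gene, changed by -0.72. The apoptosis list passed camera, with adjusted p = 0.162 with an estimated correlation.

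Cytokine and chemokine genes rose as a group. Of 26 measured NF-kappaB and inflammatory cytokine genes, 23 rose and none fell, and the same 23 is the count adjusted over the list alone. The median log2 change was 1.17. IL1B, which encodes interleukin-1 beta, rose from 1925 ± 106 to 19299 ± 906 (SD, n = 3), a change of 3.32 with a standard error of 0.06. NFKB1 (-0.12), RELB (-0.25) and TNF (0.27) did not pass the test. Camera with its preset correlation called the list (adjusted p = 4.35e-16), which had an adjusted p = 0.0796 with an estimated correlation.

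Interferon-stimulated genes moved in part. Of 44 measured, 21 rose and 2, HERC5 and IFITM1, fell, the same counts as when adjusted over the list alone. IFI27 rose by 2.03, OAS2, an antiviral RNA-sensing enzyme gene, by 1.56, SAMD9L by 1.15 and IFI44 by 0.95; the mean of all probe sets was 0.82 for OAS2 and 0.58 for IFI44. ISG15 (0.07) and OAS3 (-0.04) did not pass. As a set they passed camera, with adjusted p = 0.0796 with an estimated correlation. Of 22 antigen presentation genes, 9 rose and none fell, also when adjusted over the list alone. TAP1, a peptide transporter gene, rose by 0.72, the immunoproteasome gene PSMB8 by 0.65, HLA-B by 0.61 and HLA-C by 0.49. This list passed camera, with adjusted p = 0.113 with an estimated correlation. HLA genes have near-identical copies, so their probe sets can take signal from one another.

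Genes of matrix breakdown rose more often than they fell. Of 25 measured matrix protease and invasion genes, 14 rose and 2, MTA1 and CXCR4 (adjusted p = 0.0924 in the unmoderated test), fell, and 18 rose and 2 fell when adjusted over the list alone. The collagenase gene MMP1 rose from 689 ± 80.8 to 4192 ± 329 (SD, n = 3), a log2 change of 2.58. MMP3 rose by 2.06, the urokinase receptor gene PLAUR by 1.08 and the cathepsin gene CTSL by 0.90. TIMP1 and TIMP2, which encode inhibitors of matrix metalloproteinases, are among the 14, at 0.56 and 0.30. Camera called the list, with adjusted p = 0.107 with an estimated correlation.

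Mesenchymal and epithelial genes each moved both ways. Of 26 mesenchymal genes, 11 rose and 3 fell over all genes, the same counts as when adjusted over the list alone. The matrix genes TNC (1.53), TGFBI (1.30) and FN1 (0.82) and the fibronectin receptor gene ITGA5 (0.88) rose, and the list passed camera with adjusted p = 0.162 with an estimated correlation. VIM, the vimentin gene, had a value of -0.25 that did not pass (adjusted p = 0.0665). Without control replicate 3 it was -0.35 with an adjusted p of 0.00622. Of 27 epithelial genes, 7 rose and 4 fell, the same counts as when adjusted over the list alone. The tight junction genes CLDN1 (1.45), CLDN4 (1.01) and CLDN7 (0.98) rose, as did KRT19 (0.42), with means over all probe sets of 0.58 for CLDN4 and 0.72 for TNC, while CDH1, the E-cadherin gene, had a value of -0.28 (adjusted p = 0.298). The epithelial list did not pass camera (adjusted p = 0.259). Of 24 YAP and TGF-beta response genes, 10 rose and 3 fell, and 11 rose and 3 fell when adjusted over the list alone. TGFBR1, a TGF-beta receptor gene, rose by 0.85, INHBA by 1.03 and SKIL, an inhibitor of that pathway, by 0.84, with means over all probe sets of 0.47 for TGFBR1 and 0.54 for SKIL. This set passed camera, with adjusted p = 0.109 with an estimated correlation.

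Of 12 measured genes of ERBB receptors, their ligands and the receptor-binding proteins ERBIN and GRB7, 5 rose and 2 fell, also when adjusted over the list alone. The EGF receptor ligand genes EREG (1.54), HBEGF (1.17) and TGFA (0.71) rose, and NRG1 changed by -0.43. Averaged over all probe sets HBEGF was at 0.42, TGFA at 0.41 and NRG1 at -0.28 (adjusted p = 0.0608 for NRG1). ERBB2 had a value of -0.19 (adjusted p = 0.144). EGFR changed by -0.25 (adjusted p = 0.0191). Its adjusted p was 0.0884 with no intensity trend, 0.120 in the unmoderated test, 0.0591 without control replicate 2, 0.0554 without control replicate 3, 0.0754 without LSD1 siRNA replicate 1 and 0.0583 without LSD1 siRNA replicate 2, and the mean of its probe sets was 0.11. The list did not pass camera (adjusted p = 0.0986). Of 21 estrogen receptor and luminal genes, 8 rose and 6 fell, also when adjusted over the list alone. AGR2 (1.58), PDZK1 (1.28), CA12 (1.13, with a mean over its probe sets of 0.58) and NAT1 (0.52) rose, and ESR1, the estrogen receptor gene, had a value of 0.26 that did not pass. This list did not pass camera (adjusted p = 0.205).

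The genes of LSD1's own complexes moved both ways. Of 26 measured, 4 rose and 10 fell, KDM1A included, and 5 rose and 10 fell when adjusted over the list alone. SNAI2, a repressor that binds LSD1, rose by 0.92 and ZNF217 by 0.50, while MTA1 changed by -0.62. Of 21 enzymes and cofactors of H3K4 methylation, 2 rose and 8 fell, and 2 rose and 9 fell when adjusted over the list alone. WDR5, a shared subunit of the methyltransferases, changed by -0.75, ASH2L by -0.43 and the demethylase gene KDM2B by -0.65, while the methyltransferase gene SETD7 rose by 0.46. Of 17 neuronal genes repressed by REST, 3 rose and 3 fell, also when adjusted over the list alone; SYT1 rose by 1.85 and L1CAM by 0.77, while STMN3 changed by -0.92 and BDNF by -0.65. Their median was -0.03 and their mean 0.11, so these differ in sign. Of 12 microRNA machinery genes, 3 rose and 6 fell, also when adjusted over the list alone, with DROSHA, the nuclear processing enzyme, at -0.50, XPO5 at -0.47, TARBP2 at -0.51 and TNRC6C at -0.80. Averaged over all probe sets L1CAM was at 0.33 (adjusted p = 0.249), TARBP2 at -0.57 (adjusted p = 0.0763) and TNRC6C at -0.27 (adjusted p = 0.379). None of these 4 lists passed camera (adjusted p = 0.259, 0.157, 0.863 and 0.205 in that order).

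Of 31 glycolysis and hypoxia genes, 15 rose and 3 fell, also when adjusted over the list alone. The glucose transporter gene SLC2A3 rose by 0.99, P4HA2 by 0.77 and PFKFB3 by 0.74, while the glycolytic enzyme genes ENO1 (-0.15), LDHA (-0.19) and PKM (-0.15) did not pass. P4HA1 rose by 0.53, and the mean of its probe sets was -0.33 (adjusted p = 0.0357), while that of P4HA2 was 0.49. The list passed camera, with adjusted p = 0.399 with an estimated correlation, and 0.0544 in the preset test without control replicate 3. Of 43 oxidative phosphorylation genes, 6 rose and 12 fell, also when adjusted over the list alone, with SDHA at -0.55, UQCRC1 at -0.46 and NDUFV1 at -0.54, and NDUFB3 at 0.50. Of 24 amino acid and ATF4 response genes, 3 rose and 9 fell, also when adjusted over the list alone. SLC7A11, the cystine transporter gene, rose by 0.81, while SHMT2 changed by -0.71 and SLC7A5 by -0.58. Of 19 cholesterol synthesis genes, 4 rose, SC5D by 0.65 among them, and 5 fell, with ACAT2 at -0.60. Of 25 fatty acid genes, 7 rose and 5 fell, and 9 rose and 5 fell when adjusted over the list alone. ACSL4 rose by 0.85 and the desaturase gene SCD changed by -0.48. Averaged over all probe sets ACSL4 was at 0.03 (adjusted p = 0.918), SC5D at 0.21 (adjusted p = 0.174) and NDUFV1 at -0.32 (adjusted p = 0.124). The cholesterol counts were the same when adjusted over the list alone, and these last 4 lists did not pass camera (adjusted p = 0.519, 0.507, 0.634 and 0.677 in that order). The fatty acid list had a median of -0.05 and a mean of 0.03.

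Of 20 endoplasmic reticulum chaperone genes, 10 rose and 3 fell, also when adjusted over the list alone. DNAJB9 rose by 1.02, the vesicle coat gene SEC24D by 1.32 (0.56 with the mean of its probe sets) and PDIA3 by 0.28, while SDF2L1 changed by -0.55. The list passed camera at an adjusted p of 0.0498, with adjusted p = 0.180 with an estimated correlation. The preset test gave 0.0682 without control replicate 1, 0.0643 without LSD1 siRNA replicate 2 and 0.0662 without LSD1 siRNA replicate 3. It also lost the list with a constant of 60 (0.05004), a filter at the 60th percentile (0.0688), no intensity trend (0.0870) and the mean of all probe sets (0.142), and 4 members rose in the unmoderated test.

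Of 30 ribosomal protein genes, 6 fell and none rose, and 1 fell when adjusted over the list alone. RPL22 changed by -0.29 (adjusted p = 0.0593 in the unmoderated test), and the list's median was -0.20. The list passed camera, with adjusted p = 0.650 with an estimated correlation. The preset test gave 0.188 after quantile normalization, where the median was -0.04, 0.0899 without control replicate 1 and 0.0510 without LSD1 siRNA replicate 1. The number of lower members was 1, 2 and 23 without control replicates 1, 2 and 3, and 1, 3 and 1 without LSD1 siRNA replicates 1, 2 and 3. It was 3 after median centring, 1 with no filter, 1 with no intensity trend and 0 in the unmoderated test. Control array 1 had an ACTB 3' to 5' signal ratio of 1.74, and the other 5 arrays lay between 1.33 and 1.43. Of 11 reference genes, 4 fell, also when adjusted over the list alone, with GUSB at -0.49, SDHA at -0.55 and TBP at -0.46. That list did not pass camera (adjusted p = 0.0764), but gave 0.0457 without control replicate 3.

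Markers of other cell types were mostly not past the test. Of 12 leukocyte marker genes, 2 rose, also when adjusted over the list alone: LAPTM5 (1.20), a lysosomal membrane protein gene, and LY96 (1.79), which encodes the MD-2 partner of Toll-like receptor 4. CD14 (0.05) and CD3E (-0.36) did not pass. The leukocyte list passed camera at 0.0466, with adjusted p = 0.330 with an estimated correlation. The preset test gave 0.0544 without control replicate 3, 0.0871 without LSD1 siRNA replicate 1 and 0.0568 without LSD1 siRNA replicate 2, and 4 members rose without control replicate 1. It gave 0.123 with no filter, 0.0523 after quantile normalization and 0.0521 after median centring. Of 7 fibroblast and endothelial markers, none passed over all genes or when adjusted over the list alone, and the list had a camera adjusted p of 0.863.

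In all, 14 of the 28 lists passed camera with its preset correlation, 11 higher and 3 lower, and 2 of them, S phase and G2 and M phase, hold with an estimated correlation.

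**Figure D3:**
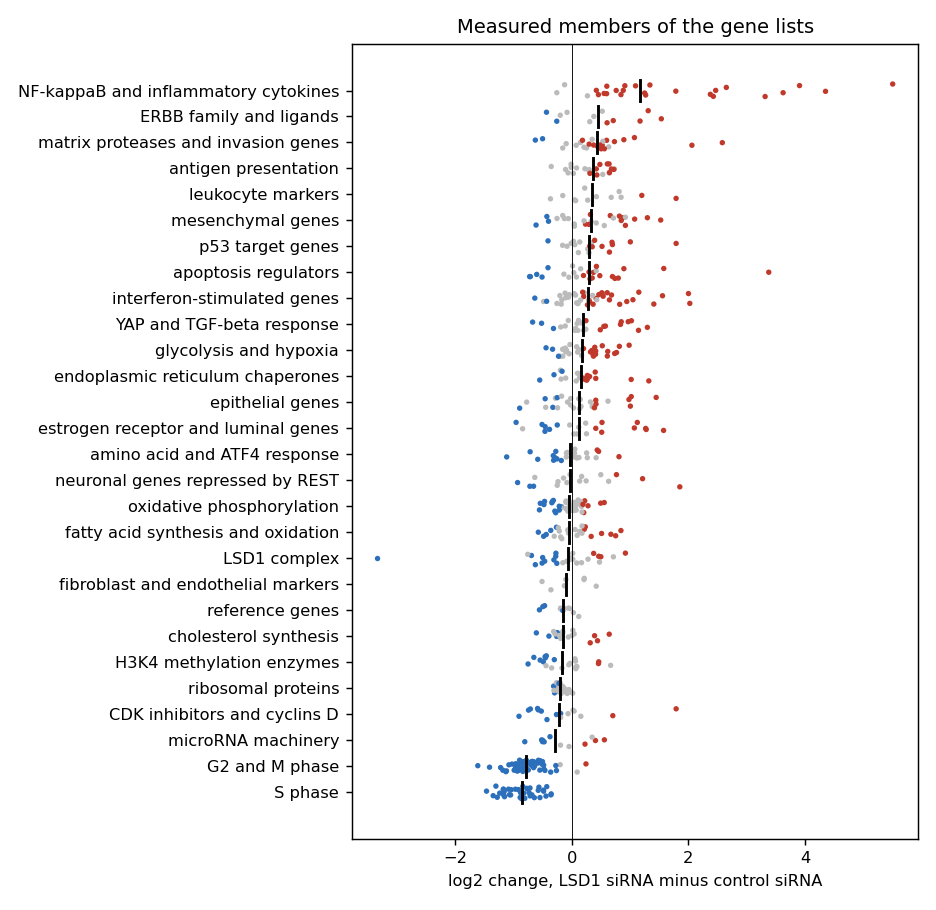
Log2 change, LSD1 siRNA minus control siRNA, of each measured member of the 28 gene lists, with 1 line per list and a black bar at its median. Red and blue members rose or fell at an adjusted p of 0.05 and grey members did not pass; the medians run from -0.86 (S phase) to 1.17 (NF-kappaB and inflammatory cytokines).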

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

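KDM1A kept its direction and its side of the threshold under every alternative run, with log2 changes from -3.48 to -3.10. The number of genes changed lay between 4255 (unmoderated test) and 5730 (without control siRNA replicate 3), except with every probe set tested, which gave 10253 probe sets, 5002 higher and 5251 lower, because more features were tested. Of the 5674 genes, 5549 were called after quantile normalization, 5428 after median centring and 4056 in the unmoderated test, all in the same direction. With the mean of all probe sets 3921 were called, 3913 in the same direction; the cause was not tested. Replicate numbers show no pairing of the samples: the deviations of same-numbered arrays correlated at 0.011, -0.012 and 0.023. All such correlations between the groups lay between -0.026 and 0.023. LSD1 siRNA arrays 1 and 3 correlated best with the control array of their number, and LSD1 siRNA array 2 with control array 1. The fit with a replicate block called 5679 genes, 5480 of them shared. The number of gene lists past the threshold was 12 to 14 in all alternatives of the preset camera test. It was 2 with an estimated correlation, which allows for members moving together and also tests on far fewer degrees of freedom. Fry, which does not compare a list with other genes, gave 22. Some lists lost with an estimated correlation had one below 0, such as p53 target genes (-0.037), apoptosis regulators (-0.028) and interferon-stimulated genes (-0.008). For those lists, members moving together does not account for the loss. The estimated test rests on the few residual degrees of freedom of the arrays, where the preset test uses those of all genes tested. This raises p even where the correlation is near 0. Reversed values were few, and for the lists the cause was not tested. With the mean of all probe sets, P4HA1 was at -0.33 and EGFR at 0.11. For P4HA1 this comes from a dim second probe set that fell from 29.4 to 4.52, while the set used here rose from 2136 to 3083. For EGFR the largest rise among its 9 probe sets, 1.04, was in a dim one that went from 22.3 to 56.2. The camera direction of the REST-repressed neuronal list, up in the main fit, turned to down with the mean of all probe sets, though the median was 0.0587. That of the fibroblast and endothelial list, down in the main fit, turned to up with a constant of 60 (median 0.018) and with no filter (median -0.0268). Leaving out each array in turn gave medians of -0.143 to 0.00283 for that list, -0.118 to 0.0666 for the neuronal list and -0.0887 to 0.00866 for oxidative phosphorylation; none of these lists had passed camera. Among the named genes, 59 further values under an alternative lost a call and 2183 kept one; of those with no call to keep, 53 stayed so and 1 gained one. Signal over background limits the dim genes: in the simulation 23 of 23 brighter genes were recovered at 2-fold and 20 of 22 at 3-fold, against 32 and 37 of all 50. These shares hold for the few changed genes of the simulation and not for the real comparison.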

Other observations

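The tests on double-stranded RNA sensing, on secreted senescence factors and on genes sharing a symbol stem were chosen after results had been seen, as were the second draw of the ribosomal test, its reading by quantile normalization and the single genes named in this part. These add 2 lists and 166 stems to the 28 lists of the main test.

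Genes that share a symbol stem were scanned as families. Of 24 nucleoporin genes (NUP), 19 fell and 1 rose, with a median log2 change of -0.51, and 9 of 10 RNA exosome genes (EXOSC) fell, with a median of -0.53. Of 49 mitochondrial large-subunit ribosomal genes (MRPL), 24 fell and 3 rose. Of 60 RAB genes, which encode GTPases of vesicle transport, 25 rose and 5 fell, with a median of 0.19. Of the 166 stems, 19 passed camera with its preset correlation, 6 higher and 13 lower, and 0 passed with an estimated correlation, where the smallest adjusted p = 0.292.

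Among single genes outside the lists, SLPI, which encodes a secreted protease inhibitor related to elafin, rose by 2.67 on the log2 scale (limma adjusted p = 7.25e-08). The complement gene C3 rose by 2.99 and SERPINB5, which encodes maspin, by 3.01, or 1.73 with the mean of its probe sets. The aldo-keto reductase genes AKR1B10 and AKR1C3 rose by 2.56 and 1.49. PTGES, which encodes a prostaglandin E synthase, rose by 1.61, and PTGS2, the cyclooxygenase-2 gene in the cytokine list, by 2.47. The groups did not overlap for any of these genes (n = 3 arrays each; limma).

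The 6 arrays have only 10 splits into groups of 3, too few for a share below 0.1. The real split gave 5674 genes and the highest of the others gave 0, so 1 of the 10 splits gave as many. For gene lists the real split gave 14 and the highest of the others 7, so again 1 split gave as many. Each of the other 9 splits keeps 2 arrays of one treatment together against 2 of the other, so part of the treatment difference stays in them, and most lists they call are also called in the real split.

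The rise of the cytokine genes was weighed against scaling of the arrays and a response to transfected double-stranded RNA. After quantile normalization the list's median was 1.19. The arrays already shared a trimmed mean of 500.1 before that step, so it does not test the scaling itself. A scaling factor moves all genes of an array the same way, and the median log2 change of all genes tested was -0.02. Scaling alone therefore does not set the cytokine genes apart from other genes. Both groups received an siRNA, and 10 genes of the double-stranded RNA sensing response had a median of 0.30 (bootstrap interval over genes 0.16 to 0.52), with 6 of 10 higher, against 1.17 for the cytokine list. All 10 belong to the interferon list, whose values had been seen and whose higher rises (IFI27 2.03, IFI44L 2.00) are not among them; all 44 members had a median of 0.28 (0.10 to 0.43). This argues against a response that raises interferon genes as far as cytokine genes, while a smaller one, or one that favours cytokine genes, may add to it. Only 1 LSD1 siRNA label is given, so an effect of its sequence on other transcripts stays open.

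The fall of the ribosomal protein genes was weighed against probe set brightness, an intensity-dependent difference between arrays, and control array 1. The list's median lay at percentile 0.33 of 10000 lists of non-member genes near it in signal, and at 0.05 in a first draw that let members in. That meets the bound set for excluding brightness but decides nothing: the random lists hold independent genes where this list has an estimated correlation of 0.83, and the list is 0.51 brighter on the log2 scale than its matches. Quantile normalization, which removes intensity-dependent differences, left a median of -0.0399. Some of these genes are among the brightest, such as RPL8 with a mean control signal of 36488. The 99th percentile of signals on control array 1 was 14457. Making the bright ends of the arrays alike would shrink a real fall too, so this median cannot tell a technical fall from a real one. Without control array 1 the median was -0.0899, against -0.20 with all arrays. That met the bound set beforehand for control array 1 as the source. An intensity-dependent difference and control array 1 may each account for part of the fall. Relative to the same matched genes, control arrays 2 and 3 also lay above the LSD1 siRNA arrays. The values were 0.058 and -0.014 against -0.074, -0.042 and -0.054 (exact permutation p = 0.1 over the 6 arrays, the smallest possible). These matches are dimmer than the list, so an intensity-dependent difference could give such values too. The values do not decide whether control array 1 alone is the source, and no biological explanation was tested.

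A candidate explanation for the fall of cell cycle genes beside the rise of cytokine genes is a senescence-like secretory state. A list of secreted senescence factors, 1 of them (ICAM1) also in the cytokine list, had a median of 0.57, with 19 of 30 higher and 4 lower (camera p = 4.34e-07, and p = 0.00456 with an estimated correlation). LMNB1, the lamin B1 gene whose loss marks senescence, changed by -0.88 (limma adjusted p = 7.85e-05). The test is weak: 15 of the 30 are in other lists, several had been seen to rise, and LMNB1 also follows the cell cycle. Growth arrest with separate cytokine induction may give the same values, and CDKN2A and CDKN2B were below the filter.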
